A study of Caenorhabditis elegans with 6 samples.

How the data were processed

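Gene expression was measured by RNA sequencing of poly(A)-selected RNA from whole N2 worms in 3 control libraries (0 µg/L diquat) and 3 diquat libraries (100 µg/L, 72 h, 20 °C), per the labels. The submitters' processing notes name fastp 0.18.0, HISAT2, StringTie 1.3.1 and RSEM and the genome build WBcel235, with no role or order. The authors deposited 1 table for the series with 20473 genes, of which 20191 carry a WormBase identifier and 282 are loci assembled from the reads, and with an annotation of pathways and biological processes.

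Per the file headers, the deposited table holds for each library a count per gene, which is a whole number and not normalized. RSEM, which gives an estimated count, is named in the submitters' processing notes, and 94 values hold a count of 0 beside an FPKM above 0, so the deposited counts were treated as estimated counts that the authors rounded before deposit. The table also holds an FPKM per gene and library, normalized by the authors for gene length and library total, per the file headers. The mean FPKM of each group, deposited by the authors, has 0.001 in place of 0. The log2 fold change deposited by the authors equals the log2 ratio of these means within 0.001 for all 20473 genes. The table also gives the authors' p-value and FDR for each gene, per the file headers. The test behind them is not given in the sources used here, nor is the strand setting of the counting. How the aligner placed reads that fit several near-identical genes is not given either, so the msp genes and other close copies are reported as uncertain.

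Everything else was computed from the deposited counts. Of the identifiers, 20105 matched the gene annotation of WBcel235 (Ensembl release 115), which gave positions and exon lengths, and 2405 genes had 0 counts in all libraries. The total count was 23390547 to 24593469 per library, so that 3 counts correspond to 0.122 to 0.128 CPM by the library total alone. Levels in CPM were scaled to the library total times its TMM factor, so this floor is only approximate beside them. The test was edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3) with TMM scaling, the default expression filter, robust dispersion and group as the only term, on all 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 CPM used a prior count of 2. Standard errors are approximate, taken from the fold change and the F statistic, and the 95% intervals were made from them. No 2 libraries of a group were within sampling noise of each other, with a chi-square per degree of freedom of 15.5 or more over genes with at least 20 counts in the pair. The 46 gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry. Camera asks whether a list ranks differently from the other genes, and fry's directional p whether its genes move one way on balance. Enrichment used a one-sided Fisher's exact test on the pathway and process terms of the deposited table with 10 to 500 tested genes, against the tested genes with any term of that kind.

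The groups, the test, the lists, the alternatives and the rule for named genes were chosen before the data were examined, except where stated. Named genes were the 8 largest rises and the 8 largest falls with an adjusted p under 0.05, a mean of at least 50 counts, groups apart and a gene name of the usual form, then from each list past camera up to 3 members past the threshold in the list's direction with a mean of at least 20 counts, and 11 sentinel genes whatever their result. The rule gave 26 genes, 16 of them past the threshold, and no rises. The lists cover antioxidant enzymes, glutathione S-transferases, SKN-1 and DAF-16 targets, heat shock and unfolded protein responses, detoxification, metals, hypoxia, stress signalling, apoptosis, DNA damage, autophagy, proteasome, ribosome, respiration, carbon and lipid metabolism, vitellogenins, collagens, molting, sperm, oocyte, germline, embryo, cell cycle, immunity, neurons, neuropeptides, muscle, pharynx, intestine, nuclear receptors, chemoreceptors, F-box proteins and histones. Mitochondrially encoded genes were matched by position and the others by symbol.

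The labels give both groups the same replicate numbers. The deviations of same-numbered libraries from their group means correlated across genes at 0.155, 0.200 and 0.459, all above 0.1, so the numbers were taken to pair the libraries and a fit with the replicate number as a block was made. Control 1 correlated more with diquat 2 (0.208) than with diquat 1, and control 2 correlated with diquat 1 at 0.088. Deviations from a group mean sum to 0, so the likeness of control 3 and diquat 3 raises the correlations among the other libraries. The values 0.155 and 0.200 are therefore not independent evidence of pairing. They cannot tell the numbered pairing of libraries 1 and 2 from the swapped one, so it rests on the labels. The biological coefficient of variation was 0.151 without and 0.0760 with the block.

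Alternatives were DESeq2 1.42.0, limma-voom, DESeq2's size factors and upper-quartile scaling in edgeR, no count filter, at least 10 counts in every library, leaving out each library, the replicate block, and limma on log2(FPKM + 1) and log2(FPKM + 0.1), whose fold changes are on that scale. Chosen after seeing the data were a length correction, which removes each library's lowess trend (span 0.3) of log2 CPM with exon length through an offset, that correction with the block, DESeq2 and limma-voom with the block, the block without each same-numbered pair, and the named-gene rule applied to the blocked fit. An exon length was known for 98.3% of the tested genes. GC content was not analysed here. Bootstrap intervals used 2000 draws of the genes of a list or set, so they hold no spread between libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

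Each step was tested on simulated data, drawn from the libraries' own means and sizes with 100 genes changed 2-fold and 100 changed 1.5-fold. For diquat against control over 13086 genes edgeR recovered 71% of the 2-fold and 27% of the 1.5-fold changes, with 9 false calls, 8.41% of all calls. limma-voom recovered 71% and 26% with 9 false calls, and DESeq2 over 13252 genes 73% and 36% with 12. With replicate effects added, over 13038 genes, the block recovered 82% and 58% with 6 false calls, and the fit without it 43% and 6% with 0. With a length trend added, over 13035 genes, the block alone made 1250 false calls, and the block with length correction 12, at 82% and 61% recovered. The added trend had a fixed size and was the same in all diquat libraries. In the data the trend differed among the same-numbered libraries. The 1250 is therefore not an error rate of the blocked fit on these data. With no change planted, 0 genes were called with the block, and 0 genes and 0 lists without it over 13066 genes. A raised list was called beside 0 of the other lists among 46 run, and a lowered term came first of 823. In these draws each gene varied independently of the others. In the data the estimated inter-gene correlation of a list was as high as 0.956 (vitellogenins). The 0 lists therefore do not show how often camera calls correlated lists wrongly.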

Results

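RNA was sequenced from whole worms of the wild-type N2 strain of Caenorhabditis elegans kept for 72 h at 20 °C with diquat dibromide monohydrate at 0 or 100 µg/L. Diquat is a bipyridyl herbicide that undergoes redox cycling and passes electrons to oxygen. Each group had 3 libraries, numbered 1 to 3 in the labels and made from poly(A)-selected RNA. The total count was 24593469, 23879907 and 23589685 in the control libraries and 23390547, 23501613 and 23569605 in the diquat libraries. Levels are given as CPM, the count scaled to the library total times its TMM factor. A floor of 3 counts corresponded to 0.122 to 0.128 CPM by the library total alone, so it is approximate beside these levels. Intervals and floors cover counting error or the spread between libraries only. The 6 vitellogenin genes, which encode yolk proteins made by adult hermaphrodites, took 10.7% to 14.7% of the counts of a library. The developmental stage at the start of exposure is not given in the sources used here. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

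The comparison asks which transcripts differed between worms at 100 µg/L diquat and worms at 0. Genes encoding cuticle collagens and genes expressed in sperm were lower with diquat, and no gene passed the test without the replicate block as higher. With that block 598 genes were called higher and 530 lower, as described below. Of 13252 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 121 fell and 0 rose, and 102 of the 121 fell by more than 2-fold. Cuticle collagens contributed 39 of the 121 and sperm genes 24, and 58 belonged to neither list. Adjusted p-values below are Benjamini-Hochberg values from this edgeR test for genes and from camera for gene lists, unless another test is named.

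The named genes with the largest falls were collagens and sperm-associated genes. col-63 (chromosome I, 8243694 to 8244963, WBcel235), a collagen of the adult cuticle, fell from 13.4 ± 1.12 to 3.79 ± 0.765 CPM (mean ± SD, n = 3 in each group; log2 fold change -1.82, standard error 0.19, edgeR adjusted p = 0.00211). col-120 (chromosome IV, 9260610 to 9261787) fell from 6.18 ± 0.722 to 1.75 ± 0.318 CPM (log2 fold change -1.82, edgeR adjusted p = 0.00292). col-37 (chromosome V, 12166706 to 12167753) fell by 2.06 on the log2 scale (edgeR adjusted p = 0.00353). gipc-2 and msd-1 both lie on chromosome IV, at 10026413 to 10027666 and at 10022349 to 10022678. gipc-2 fell from 5.56 ± 0.528 to 1.70 ± 0.157 CPM (log2 fold change -1.71, edgeR adjusted p = 0.00317), and msd-1, which encodes a protein with a major sperm protein domain, fell by 1.79 on the log2 scale (edgeR adjusted p = 0.00852). ssp-11 (chromosome IV, 4999485 to 4999814), of the sperm-specific family class P, had 165, 84 and 90 counts in the control libraries and 13, 0 and 0 in the diquat libraries (log2 fold change -4.66, edgeR adjusted p = 0.00641; 0.567 with DESeq2). Its size rests on the 13 counts of diquat 1: without that library it was -9.81, from 0 counts on the diquat side. col-40 (chromosome II, 1104942 to 1106964) and col-2 (chromosome IV, 10084439 to 10085451) fell by 1.83 and by 1.74 on the log2 scale (edgeR adjusted p = 0.0152 and 0.0380).

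All 121 genes had the 3 diquat libraries on the same side of the 3 control libraries, as had 10.75% of all tested genes, where chance gives 10%. The 121 were chosen by a test on these same libraries, so their separation largely follows from that choice and is no separate evidence. At an unadjusted p under 0.05 edgeR had 204 genes higher and 620 lower. limma-voom called 0 genes higher and 118 lower, DESeq2 2 higher and 156 lower, and the authors' deposited table, at its FDR under 0.05, 2 higher and 154 lower. DESeq2 and that table each lacked 2 of the 121 falls. The 2 higher genes of DESeq2 and of the authors' deposited table were Y59A8B.25 and C13A2.3, chosen here after their values were seen. They had 0 counts in all control libraries and 15, 19 and 3 and 4, 9 and 24 counts in the diquat libraries, below the count filter of the edgeR test. Only the falls without control 1 (71), control 2 (38) and diquat 1 (27), the 2-fold changes without control 2 (37), control 3 (67) and diquat 1 (26), and the rises without diquat 3 (1, Y59A8B.25) differed from the counts over all 6 libraries by more than 1.5 times. col-63, col-120, col-37, gipc-2 and ssp-11 stayed past the edgeR threshold without any of the libraries. msd-1 did not without diquat 1 (adjusted p = 0.120), and col-40 (0.0545, 0.0885 and 0.0964) and col-2 (0.161, 0.155 and 0.132) did not without control 1, control 2 or diquat 1.

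With the replicate number as a block, edgeR called 598 genes higher and 530 lower, with 7 higher and 213 lower by more than 2-fold. These calls rest on pairing by number, which the correlations between libraries clearly show only for control 3 and diquat 3. All 121 falls were among the 530. limma-voom with the block called 606 higher and 541 lower, and DESeq2 with the block 126 and 268. The blocked edgeR fit called 15 higher and 181 lower without pair 1, 329 and 333 without pair 2, and 436 and 482 without pair 3. The 598 rises had a median log2 fold change of 0.33, and 79 of the 598 had the diquat libraries all above the control libraries, against 387 of the 530 falls on the opposite side. The largest blocked rises under the naming rule were cdh-10, pgp-6, dod-21, mab-5, fat-5, dpy-19, haf-9 and inx-17, with blocked log2 fold changes from 0.88 to 0.51 (blocked adjusted p = 0.00180 to 0.0468; 0.227 to 0.527 without the block). With the length trend also removed cdh-10, pgp-6 and dpy-19 lost the blocked call (0.0505, 0.0519 and 0.0663). Where a call below is made only with this block, it is given as a blocked call. A call made with the block and the length trend removed is given as blocked and length-corrected. For some genes that fit gave far smaller adjusted p-values at like fold changes. For col-63 the edgeR adjusted p was 1.13e-32, against 2.56e-10 with the block alone, at a log2 fold change of -1.83 in each. Calls gained or lost in that fit therefore cannot be put down to length alone. Genes named below for such calls were chosen after their values were seen.

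**Figure D1:**
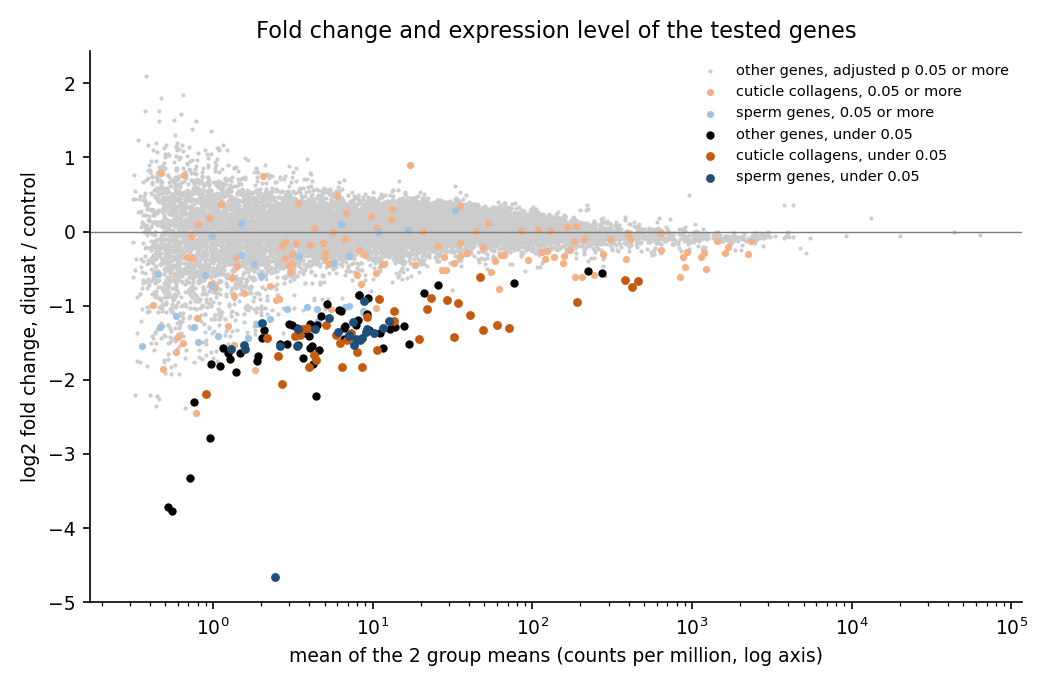
Log2 fold change (diquat over control) of each tested gene against the mean of the group means in CPM (log axis), with genes past an edgeR adjusted p of 0.05 in dark colours. The 121 genes past the threshold all lie below 0, and 39 are cuticle collagens and 24 sperm genes.

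Fold changes were higher for longer transcripts. The Spearman correlation of log2 fold change with exon length was 0.318 across genes, which are not independent replicates. The median log2 fold change was -0.12 in the shortest length decile of the genes and 0.12 in the longest. Between these deciles the trend differed among the same-numbered libraries, from -0.31 to 0.21 for number 1, from -0.07 to 0.12 for number 2 and from -0.01 to 0.02 for number 3. Number 3 was highest in decile 8, at 0.07. The median exon length was 1416 nucleotides over the tested genes, 993.5 over the 121 falls, 2501 over the 598 blocked rises and 1034 over the 530 blocked falls. With each library's length trend removed, 92 genes fell and 1 rose, and 91 of the 92 were among the 121. The gene that rose was spp-17 (log2 fold change 0.59, edgeR adjusted p = 0.0190; 0.38 and 0.417 without the correction), of the saposin-like family, chosen after its values were seen.

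**Figure D2:**
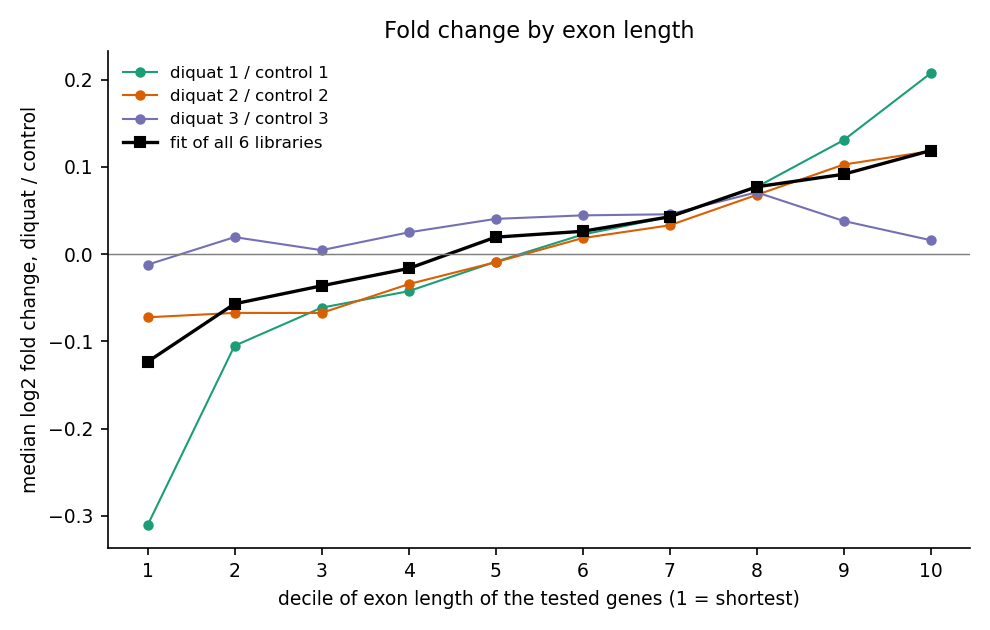
Median log2 fold change (diquat over control) of the tested genes in each decile of exon length, shortest first, for the fit of all 6 libraries (squares) and for the same-numbered libraries (circles). The medians run from -0.12 to 0.12 in the fit and from -0.31 to 0.21 for the libraries numbered 1.

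Collagens form the cuticle, the extracellular layer that covers the worm and is rebuilt at each molt. Of 159 cuticle collagens tested, 39 fell and 0 rose, and adjusted over the list alone 75 fell and 1 rose (col-41, chosen after its values were seen). The list had a median log2 fold change of -0.44 and ranked below the other genes (camera adjusted p = 1.35e-35; adjusted p = 0.713 with an estimated correlation). col-37 and col-40 are given above, and col-185 (chromosome X, 13510035 to 13511097) fell by 2.19 on the log2 scale, at only 6 to 44 counts per library (edgeR adjusted p = 0.0409). Of the 3 most abundant collagens, chosen after their values were seen, sqt-3 had a log2 fold change of -0.12, col-140 of -0.30 and col-119 of -0.21 (edgeR adjusted p = 0.879, 0.819 and 0.819; blocked 0.0847, 2.26e-05 and 0.00307). Without control 2 or diquat 1 the count of falls was 15 or 12, and with the block 91 collagens fell and 2 rose (col-41 and col-17). The length trend removed, 34 fell. col-185 lost its call without control 1, control 2, diquat 1, diquat 2 or diquat 3 (edgeR adjusted p = 0.10 to 0.234) and with the length trend removed (0.0539).

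The 7 adult-stage collagens, all of them also in the cuticle collagen list, were lower as a group. Of the 7, 3 fell (col-63, col-7 and bli-2), 6 fell adjusted over the list alone and all 7 fell with the block, and the list median was -1.04 (camera adjusted p = 1.49e-10; adjusted p = 0.514 with an estimated correlation). col-7 (chromosome I, 7401132 to 7402761) fell from 5.11 ± 0.860 to 2.05 ± 0.70 CPM (n = 3; log2 fold change -1.32, edgeR adjusted p = 0.0329), and bli-2 (chromosome II, 5651394 to 5652434), named for blistering of the cuticle, fell from 3.17 ± 0.656 to 1.17 ± 0.250 CPM (log2 fold change -1.44, edgeR adjusted p = 0.0290). bli-6 and rol-1, named for blistered and rolling worms and outside the list, fell by 1.52 and by 1.56 on the log2 scale (edgeR adjusted p = 0.00290 and 0.00641), chosen after their values were seen. The molting list, of genes for shedding and rebuilding the cuticle, had 0 of 54 members past the edgeR test and a median of -0.09 (camera adjusted p = 0.0212; adjusted p = 0.713 with an estimated correlation). With the block grl-20, grl-25, grl-16, grl-5, grl-7 and ptr-23 fell and fbn-1 and ptr-4 rose. Both rises were lost in the blocked and length-corrected fit (edgeR adjusted p = 0.137 and 0.196), where 10 members fell and 0 rose. The molting call was lost without control 1 (adjusted p = 0.136, median -0.04) or diquat 3 (0.131). bli-2 lost its edgeR call without control 2, control 3, diquat 1 or diquat 3 (adjusted p = 0.0655 to 0.194), and col-7 without control 1, control 2, control 3, diquat 1 or diquat 3 (0.0586 to 0.204).

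Genes expressed in sperm formed the other large group. Of 55 sperm genes tested, 24 fell and 0 rose, and 41 fell adjusted over the list alone. The list median was -1.22 (camera adjusted p = 4.40e-48; adjusted p = 0.314 with an estimated correlation). It was the 1 list past fry's directional test (adjusted p = 0.0347), a call lost with the block (0.108), with the length trend removed (0.0729) and with both (0.103). Of 27 tested msp genes, which encode the major sperm proteins that move nematode sperm, 18 fell with a median of -1.31, and both sperm-enriched phosphatase genes gsp-3 and gsp-4 fell (log2 fold change -1.31 and -1.16, edgeR adjusted p = 0.0138 and 0.0182). ssp-11, ssp-16 and ssp-34 fell among 8 ssp genes and nspd-1 among 7 nspd genes, with family medians of -1.38 and -1.24. The 10 spe genes, identified through defects in spermatogenesis, had 0 past the test and a median of -0.04, and with the block 1 rose (spe-39; lost in the blocked and length-corrected fit, adjusted p = 0.0610). fer-1 had a log2 fold change of -1.14 (edgeR adjusted p = 0.561).

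The msp genes are near-identical copies, so the split of counts between them is uncertain, as is each single msp value. Summed over 31 msp genes, the level was 236, 263 and 223 CPM in the control libraries and 98.4, 123 and 78.4 CPM in the diquat libraries. ssp-16 (chromosome I, 6102067 to 6102396) fell from 1.94 ± 0.127 to 0.646 ± 0.137 CPM (n = 3; log2 fold change -1.58, edgeR adjusted p = 0.0329), and ssp-34 (chromosome IV, 10738279 to 10738602) by 1.59 on the log2 scale (edgeR adjusted p = 0.0437). Outside the list, msd-2, msd-4, gipc-1, the sperm-specific class Q genes ssq-1, ssq-2, ssq-3 and ssq-4 and the sperm chromatin genes spch-2 and spch-3 fell as well, chosen after their values were seen. Their log2 fold changes lay between -1.56 (msd-2) and -1.26 (ssq-3). Sperm genes are short, with a median exon length of 384 nucleotides, and with the length trend removed 16 fell, with a median of -1.04. The count of sperm genes that fell was 10 without control 2, 14 without control 3 and 5 without diquat 1, and 36 with the block. With the length trend removed ssp-16 and ssp-34 lost their calls (edgeR adjusted p = 0.0881 and 0.148). ssp-16 also lost its call without control 1, control 2, control 3, diquat 1 or diquat 3 (edgeR adjusted p = 0.0655 to 0.204) and ssp-34 without any of the 6 libraries (0.0595 to 0.257).

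**Figure D3:**
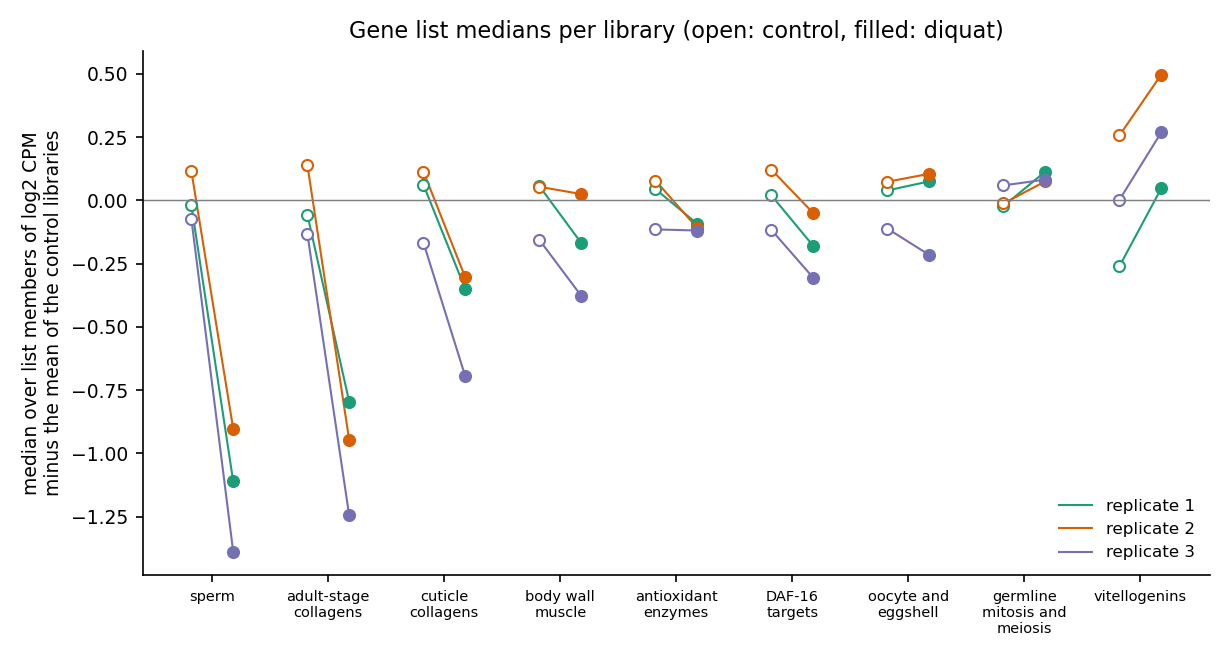
Median over the members of 9 gene lists of log2 CPM minus the mean of the control libraries, per library (open circles control, filled circles diquat, lines joining libraries of the same number). The sperm, adult-stage collagen and cuticle collagen medians are below those of the control libraries in all 3 diquat libraries, with list medians of -1.22, -1.04 and -0.44 in the fit of all libraries.

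Across the fixed lists, 19 of 46 passed camera, 14 lower and 5 higher. None of the 19 passed with an estimated correlation, 9 passed with the length trend removed and 7 without control 1. With the block 24 passed, 18 lower and 6 higher, and 0 with the block and an estimated correlation. With the block and the length trend removed 15 passed, 11 of the 19 among them, and the blocked calls of SKN-1 phase II targets (camera adjusted p = 0.151), vitellogenins (0.287), C-type lectins (0.0931) and mitochondrially encoded respiratory chain genes (0.0931) were lost.

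Antioxidant and stress-response genes showed small differences. Of 27 antioxidant enzyme genes 0 passed the edgeR test, with or without the block, and ctl-3 and sod-4 fell in the blocked and length-corrected fit (adjusted p = 0.00337 and 0.0370). Of the 27, 22 had a negative log2 fold change, with a median of -0.09 (camera adjusted p = 0.0443; adjusted p = 0.713 with an estimated correlation). sod-3 (chromosome X, 17092753 to 17094306), the inducible mitochondrial superoxide dismutase, was at 1.66 ± 0.271 CPM in control and 1.51 ± 0.366 CPM with diquat (n = 3; log2 fold change -0.14, 95% interval -0.78 to 0.50, edgeR adjusted p = 0.933), and 0.01 without control 3. The peroxisomal catalase ctl-2 (chromosome II, 14299556 to 14302027) was at 143 ± 11.8 and 137 ± 10.6 CPM (log2 fold change -0.07, 95% interval -0.31 to 0.18, edgeR adjusted p = 0.914). sod-1, sod-2 and prdx-2, chosen after their values were seen, had log2 fold changes of -0.08, -0.11 and -0.09 (edgeR adjusted p = 0.893, 0.853 and 0.895). The antioxidant call was lost with the length trend removed (camera adjusted p = 0.343) and without control 1, control 2, diquat 1, diquat 2 or diquat 3 (0.0543 to 0.308). Its median was -0.03 with the length trend removed and -0.05, -0.14 and -0.14 without control 2, control 3 and diquat 3. The list's median exon length was 797 nucleotides.

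Glutathione S-transferases, which conjugate glutathione to electrophiles, had 0 of 37 members past the edgeR test and a median of -0.13 (camera adjusted p = 0.0197; adjusted p = 0.713 with an estimated correlation), and gst-5 and gst-10 fell with the block. The call was lost without control 1, control 2, diquat 2 or diquat 3 (camera adjusted p = 0.0606 to 0.351) and with the length trend removed (0.225), at a median exon length of 749 nucleotides. The median was -0.08 without control 1 and -0.07 with the length trend removed. Phase II targets of the oxidative stress transcription factor SKN-1 had a median of -0.16 over 16 members, 0 of which passed the edgeR test (camera adjusted p = 0.0530; blocked adjusted p = 0.0415, and 0.555 with the block and an estimated correlation), with gst-5 and gst-10 again lower in the block. gst-4 (chromosome IV, 10142225 to 10143099), a common reporter of SKN-1 activity, had 8 to 20 counts per library and a log2 fold change of -0.48 (edgeR adjusted p = 0.846), with a 95% interval of -1.54 to 0.57 that includes a 2-fold fall. gcs-1 (chromosome II, 9035562 to 9038301), the rate-limiting enzyme of glutathione synthesis, was at 40.2 ± 6.74 and 46.0 ± 2.39 CPM (log2 fold change 0.20, 95% interval -0.10 to 0.49, edgeR adjusted p = 0.819). skn-1 itself (chromosome IV, 5651039 to 5660384) had a log2 fold change of 0.09 (95% interval -0.14 to 0.33, edgeR adjusted p = 0.868), which was -0.003 with the length trend removed.

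Targets of DAF-16, the forkhead factor of insulin signalling, ranked lower as a list, with negative values for all 13 members and a median of -0.22 (camera adjusted p = 0.00150; adjusted p = 0.713 with an estimated correlation). The call held without each library in turn and with the length trend removed (camera adjusted p = 0.0174, median -0.13). The list did not pass fry's directional test (adjusted p = 0.284). Its library median was -0.05 in diquat 2, above the -0.12 of control 3. Of the 13 members, 10 are also in other lists. The metallothionein gene mtl-1 (chromosome V, 6691371 to 6691863), which binds metals, was the 1 member that fell, from 31.8 ± 2.77 to 19.3 ± 3.43 CPM (n = 3; log2 fold change -0.72, edgeR adjusted p = 0.0469), and with the block hsp-16.2, icl-1, lys-8 and dod-6 fell too (dod-6 not in the blocked and length-corrected fit, adjusted p = 0.181). daf-16 (chromosome I, 10750498 to 10776703) had a log2 fold change of -0.03 (95% interval -0.27 to 0.21, edgeR adjusted p = 0.969), which was 0.04 without diquat 3. In the metal and iron list, with a median of -0.19 over 12 members, mtl-1 and ftn-1 fell, and cdr-1 and ftn-2 also adjusted over the list alone (camera adjusted p = 0.00770; adjusted p = 0.713 with an estimated correlation; 0.0893 without control 1). Its median was -0.11 without control 2. ftn-1 (chromosome V, 7546468 to 7547579), an iron-storing ferritin, fell from 12.1 ± 0.801 to 6.52 ± 0.0876 CPM (log2 fold change -0.89, edgeR adjusted p = 0.0140), and with the block ttm-1 fell as well. mtl-1 lost its call with the length trend removed (edgeR adjusted p = 0.160), with size factors from DESeq2 (0.0547) and without control 1, control 2, control 3, diquat 1 or diquat 3 (0.0551 to 0.316), and ftn-1 without control 2 (0.124) or diquat 1 (0.121).

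No member of the fixed heat shock and unfolded protein response lists passed the edgeR test. Outside these lists abu-7, of the deposited term for the endoplasmic reticulum unfolded protein response, fell (log2 fold change -1.78, edgeR adjusted p = 0.0380, mean of 23 counts). It was chosen after its values were seen. The 17 cytosolic heat shock genes had a median of -0.07 (camera adjusted p = 0.149), and with the block hsp-16.11 and hsp-16.2 fell, while hsp-16.48 and hsp-16.49 had identical counts, so their reads cannot be assigned to either copy. F44E5.5 and hsp-110 also fell in the blocked and length-corrected fit (adjusted p = 0.0104 and 0.0305). hsp-16.2 (chromosome V, 1804334 to 1804957) was at 18.05 ± 4.34 and 13.3 ± 2.37 CPM (n = 3; log2 fold change -0.44, 95% interval -0.86 to -0.02, edgeR adjusted p = 0.769; blocked 0.0126). The mitochondrial chaperone gene hsp-6 (chromosome V, 4824124 to 4826760) had a log2 fold change of 0.02 (95% interval -0.25 to 0.30, edgeR adjusted p = 0.977), which was -0.07 with the length trend removed, -0.02 without control 3 and -0.05 without diquat 2. The endoplasmic reticulum chaperone gene hsp-4 (chromosome II, 7350112 to 7352645) had one of 0.03 (95% interval -0.19 to 0.25, edgeR adjusted p = 0.962), which was -0.05 with the length trend removed and -0.003 without diquat 1. The lists of the mitochondrial and the endoplasmic reticulum unfolded protein response had medians of 0.04 over 13 members and 0.02 over 26 (camera adjusted p = 0.675 and 0.380), negative with upper-quartile scaling and with the length trend removed, and 1 member of each rose with the block (lonp-1 and cnx-1). Both calls were lost in the blocked and length-corrected fit (edgeR adjusted p = 0.161 and 0.0836).

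**Figure D4:**
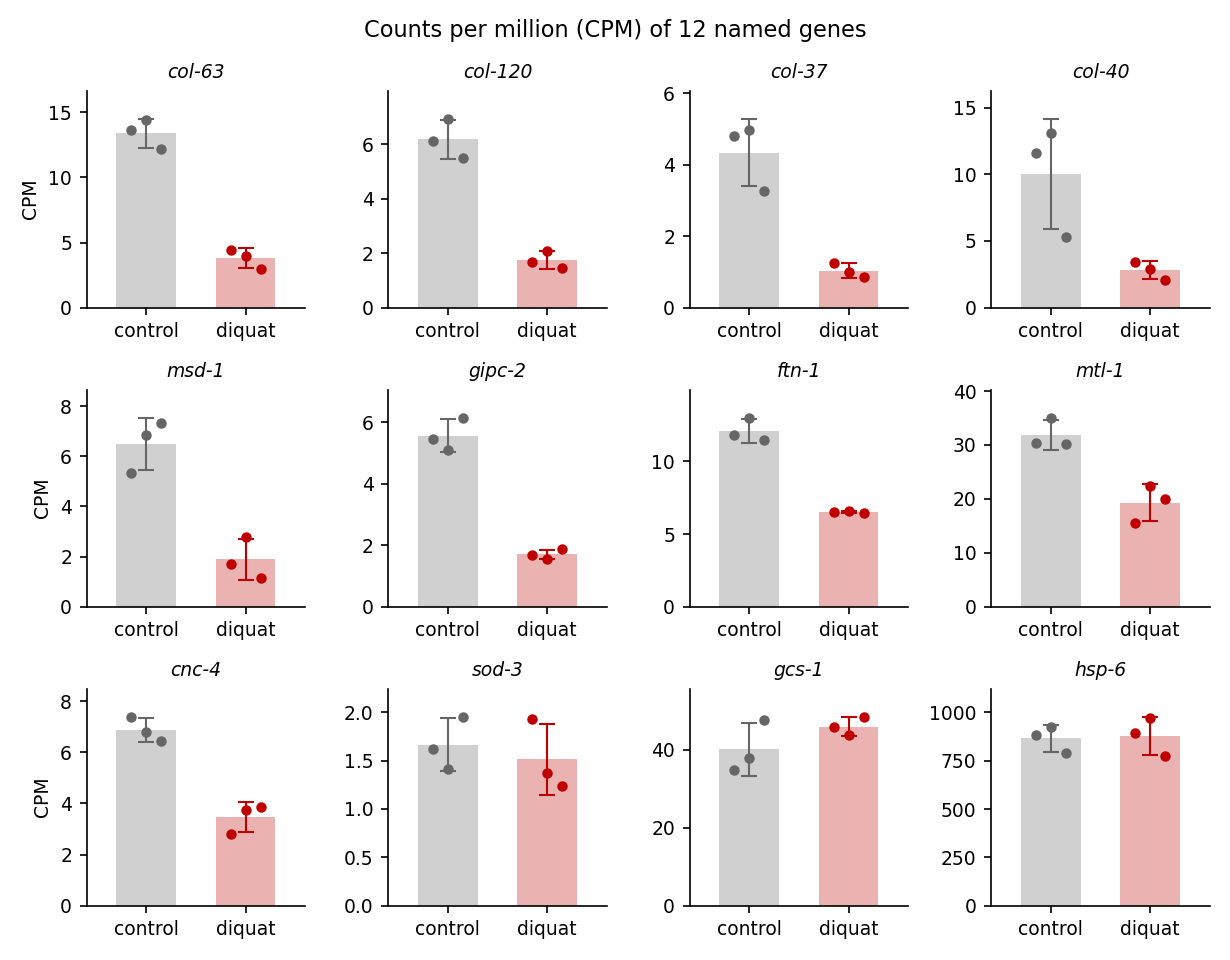
CPM of 12 named genes in each library (points), with the group mean (bar) and SD (error bar), n = 3 per group. col-63 falls from 13.4 to 3.79 and ftn-1 from 12.1 to 6.52, while sod-3 is at 1.66 and 1.51 with overlapping points.

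Yolk, oocyte and embryo genes had list medians near or above 0. Vitellogenins had 0 of 6 members past the edgeR test and a median of 0.27 (camera adjusted p = 0.0622; blocked adjusted p = 0.0276, and 0.555 with the block and an estimated correlation). With the block vit-1, vit-3, vit-4 and vit-5 rose (blocked log2 fold change 0.49, 0.36, 0.36 and 0.19). In the blocked and length-corrected fit vit-5 lost its call (edgeR adjusted p = 0.491) and vit-2 fell (log2 fold change -0.17, edgeR adjusted p = 0.0229). vit-2 (chromosome X, 5101042 to 5106169), the most abundant of them, was at 64472 ± 12612 and 62336 ± 12262 CPM (n = 3; log2 fold change -0.05, 95% interval -0.48 to 0.38, edgeR adjusted p = 0.968), which was 0.12, 0.04 and 0.02 without control 2, diquat 1 and diquat 3. Vitellogenin genes are long, with a median exon length of 4935 nucleotides, and with the length trend removed their median was 0.15. Oocyte and eggshell genes had a median of -0.001 over 29 members with a mean of 0.01, positive with DESeq2's size factors (camera adjusted p = 0.873), and chs-1 rose with the block. Early embryo genes had a median of -0.001 and a mean of 0.02 over 7 members, with a median of 0.002 under DESeq2's size factors and 0.03 with the length trend removed (camera adjusted p = 0.842).

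Germline, DNA damage and cell cycle lists ranked higher, with 0 members past the edgeR test. Germline mitosis and meiosis genes had a median of 0.10 over 36 members, cell cycle and DNA replication genes 0.12 over 24 and DNA damage response genes 0.17 over 24 (camera adjusted p = 0.0212 for each; adjusted p = 0.713 for each with an estimated correlation). With the block spo-11, him-8, him-17 and zim-2 rose in the first, cdc-6, cya-1 and orc-1 in the second and exo-1, mre-11 and atl-1 in the third. In the blocked and length-corrected fit zim-2 (edgeR adjusted p = 0.0525), orc-1 (0.0715), mre-11 (0.137) and atl-1 (0.161) lost these calls, and mcm-4 of the cell cycle list fell (0.0115). Their median exon lengths were 2158.5, 2049 and 1869.5 nucleotides, and with the length trend removed the medians were 0.03, 0.06 and 0.08 (camera adjusted p = 0.242, 0.171 and 0.119), and with the block as well only the DNA damage list passed (0.277, 0.235 and 0.0462; 0.560 for the DNA damage list with an estimated correlation). The germline call was also lost without control 1, control 2, diquat 1 or diquat 2 (camera adjusted p = 0.0534 to 0.133), the cell cycle call without control 1, diquat 1 or diquat 2 (0.0513 to 0.127) and the DNA damage call without control 1, control 2 or diquat 3 (0.0534 to 0.261). The DNA damage median was 0.08, 0.26 and 0.06 without control 1, control 3 and diquat 3.

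Immune effector lists had negative medians. Lysozymes and antimicrobial peptides had a median of -0.13 over 55 members (camera adjusted p = 0.000551; adjusted p = 0.713 with an estimated correlation). The antimicrobial peptide gene cnc-4 (chromosome V, 1447195 to 1447707) fell from 6.87 ± 0.486 to 3.48 ± 0.581 CPM (n = 3; log2 fold change -0.98, edgeR adjusted p = 0.0340), nlp-31 and nlp-34 also fell adjusted over the list alone, and with the block 11 fell and spp-17 and lys-4 rose. In the blocked and length-corrected fit 7 fell and spp-17, lys-4 and spp-23 rose. These are short transcripts, with a median exon length of 472 nucleotides, and the camera call was lost with the length trend removed (adjusted p = 0.451, median -0.03) or without control 1 (0.0893), and the median was -0.21 without control 3. Lost too was the call of cnc-4 with the length trend removed (edgeR adjusted p = 0.0696) and without control 1, control 2, control 3, diquat 1 or diquat 2 (0.0630 to 0.218). Infection response genes had 0 of 17 members past the edgeR test and a median of -0.28 (camera adjusted p = 0.0212; adjusted p = 0.713 with an estimated correlation; 0.284, 0.160 and 0.133 without control 3, diquat 1 and diquat 2). The median was -0.12, -0.15, -0.13 and -0.53 without control 3, diquat 1, diquat 2 and diquat 3, and -0.15 over members with at least 10 counts in every library. irg-5 fell with the block. Of 109 C-type lectins, 2 fell, clec-13 and clec-15, whose counts were identical in every library, so the reads of the 2 genes cannot be told apart and their values are uncertain. The lectin list had a median of -0.07 (camera adjusted p = 0.0839; blocked adjusted p = 0.0295, and 0.555 with the block and an estimated correlation), and with the block 13 fell and clec-97 and clec-160 rose.

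Neuropeptide and insulin-like peptide genes, which encode secreted signals, had 99 negative and 16 positive values and a median of -0.19, with 0 members past the edgeR test (camera adjusted p = 1.08e-08; adjusted p = 0.713 with an estimated correlation). Of the members, 9 are also among the antimicrobial peptides. The call held without each library and with the length trend removed (camera adjusted p = 0.0171; median -0.09), at a median exon length of 572 nucleotides. The list did not pass fry's directional test (adjusted p = 0.455). Its library medians in diquat 1 and diquat 2 (-0.15 and -0.10) lay above that of control 3 (-0.16). With the block 8 members fell, among them nlp-31, nlp-34, flp-3 and flp-14 (flp-14 not in the blocked and length-corrected fit, adjusted p = 0.125, where ins-19 rose). Body wall muscle genes had a median of -0.18 over 15 members, 0 of which passed the edgeR test (camera adjusted p = 0.0212; adjusted p = 0.713 with an estimated correlation). With the block 8 of them fell, among them the myosin gene unc-54, the tropomyosin gene lev-11 and the troponin genes tnt-2 and unc-27. The muscle call was lost without control 1, control 2, diquat 1 or diquat 3 (camera adjusted p = 0.0538 to 0.192), and the median was -0.29 without diquat 2.

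Genes for protein synthesis and respiration differed little. Cytosolic ribosomal protein genes had negative values in 79 of 80 members with a median of -0.08, which was 0.02 with the length trend removed (camera adjusted p = 0.00127, and 0.299 with the length trend removed; adjusted p = 0.743 with an estimated correlation), at a median exon length of 521.5 nucleotides. Nuclear-encoded respiratory chain genes had a median of -0.09 over 47 members (camera adjusted p = 0.0201, and 0.361 with the length trend removed; adjusted p = 0.741 with an estimated correlation), and cox-6B fell with the block. That call was lost in the blocked and length-corrected fit (edgeR adjusted p = 0.275), where atp-1, sdha-1 and nuo-5 fell (0.0446, 0.0155 and 0.0128). The ribosomal call was lost without control 1, control 2 or diquat 3 (camera adjusted p = 0.149, 0.0501 and 0.405), as was the respiratory one (0.270, 0.191 and 0.533). Without control 1, control 2, control 3, diquat 2 and diquat 3 the ribosomal median was -0.04, -0.05, -0.13, -0.16 and -0.03, and the respiratory median -0.05, -0.04, -0.15, -0.16 and -0.04 (-0.04 with the length trend removed). Mitochondrially encoded respiratory chain genes had a median of -0.16 over 9 members, all negative (camera adjusted p = 0.109; blocked adjusted p = 0.0393, and 0.555 with the block and an estimated correlation), and 3 fell with the block, for cytochrome oxidase subunits I and III and NADH dehydrogenase subunit 1.

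Among genes for the modification and export of foreign compounds, UDP-glucuronosyltransferases ranked higher, with 33 of 48 positive values, 0 members past the edgeR test and a median of 0.20 (camera adjusted p = 0.0191; adjusted p = 0.713 with an estimated correlation). With the block ugt-39, ugt-47 and ugt-62 rose. The median was 0.42 without control 3 and 0.32 without diquat 2. The call was lost without diquat 3 (camera adjusted p = 0.311, median 0.02) and with the length trend removed (0.0913, median 0.13), and not with the block and the length trend removed (0.0462, median 0.15; 0.560 with an estimated correlation). ABC transporters had 0 of 42 members past the edgeR test and a median of 0.08, which was -0.02 with the length trend removed (camera adjusted p = 0.0424, and 0.629 with the length trend removed; adjusted p = 0.713 with an estimated correlation), at a median exon length of 3972.5 nucleotides. With the block haf-9, pgp-6, abcf-1, mrp-1 and mrp-5 rose, and in the blocked and length-corrected fit only haf-9 and abcf-1 did, while abt-4 fell. The list's call was lost without control 1, control 2, diquat 1, diquat 2 or diquat 3 (camera adjusted p = 0.0860 to 0.601). Its median was 0.22 without control 3 and 0.14 without diquat 2. Cytochromes P450 had 0 of 55 members past the edgeR test and a median of 0.03, negative with upper-quartile scaling and with the length trend removed (camera adjusted p = 0.753), and cyp-34A2 and cyp-35A4 fell with the block, and cyp-35A2 too in the blocked and length-corrected fit.

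Among the terms of the annotation in the deposited table, 1 of 825 was enriched among the falls by Fisher's exact test with Benjamini-Hochberg adjustment, extracellular matrix organization, with 4 of its 35 tested genes (col-36, col-71, col-73 and col-120; adjusted p = 0.00142). Only 22 of the 121 falls carried any process term, so most of the falls were outside the test of processes. With the block 33 terms passed, 17 among the falls and 16 among the rises. The former included extracellular matrix organization (12 of 35), innate immune response (23 of 190) and muscle contraction (6 of 22). The term for the unfolded protein response of the endoplasmic reticulum (9 of 53) was among them through F53B1.4, F59F4.2, abu-1, abu-6, abu-7, abu-15, pqn-74, col-109 and hsp-16.11, while hsp-4 was not called. The terms among the blocked rises included DNA repair (25 genes), RNA interference (12 genes) and meiotic cell cycle (18 genes), and with the length trend also removed 0 terms passed among the rises and 34 among the falls.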

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

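Tests that remove the trend with exon length, DESeq2 or limma-voom with the replicate block, and the block without 1 pair were chosen after the results were seen. The 0 genes higher were 2 with DESeq2 and with no count filter, and 1 with limma on log2(FPKM + 0.1), with the length correction and, at most, without 1 library (lowest 0). The 121 genes lower ranged from 27 to 116 and the 102 changed over 2-fold from 26 to 99 when 1 library was left out. All 121 kept a negative fold change there, which largely follows from their groups being apart over all libraries. With the replicate block 598 genes were higher, 530 lower and 220 over 2-fold, with DESeq2 and the block 126 higher and 268 lower, and with limma-voom and the block 606, 541 and 223. The block with the length correction gave 451 higher, 822 lower and 232 over 2-fold. Adjusted p-values of that fit were far smaller for some genes at like fold changes, so these counts do not reflect length alone. The blocked fit gave 15 genes higher without pair 1, 329 higher, 333 lower and 178 over 2-fold without pair 2, and 436, 482 and 162 without pair 3. With fewer libraries such fits have fewer degrees of freedom, and for the other differences the cause was not tested. The 19 gene lists were 0 with an estimated correlation, 1 with fry, 10 with the length correction (9 of the 19, and the histones) and 7 to 23 without 1 library. The 1 enriched term became 33 with the block and 34 with the block and the length correction. The fry call, of sperm genes (adjusted p = 0.0347), was lost with the block (0.108), with the length correction (0.0729) and with both (0.103). The ribosomal protein median turned to 0.0194 with the length correction and to 0.0187 with it and the block. Of the sentinel genes only mtl-1 was past the threshold. Among the other sentinel genes the length correction turned hsp-6 to -0.0668, hsp-4 to -0.0506 and skn-1 to -0.00349. Leaving out 1 library gave values of -0.347 to 0.00844 for sod-3, -0.0528 to 0.0919 for hsp-6, -0.00339 to 0.0465 for hsp-4, -0.222 to 0.117 for vit-2, -0.0862 to 0.0425 for daf-16, -0.957 to -0.231 for gst-4, 0.103 to 0.360 for gcs-1, -0.5996 to -0.252 for hsp-16.2, -0.130 to -0.00300 for ctl-2 and 0.0321 to 0.142 for skn-1. All 19 lists kept direction and call with DESeq2's size factors, 18 with at least 10 counts in every library (molting: adjusted p = 0.0555 from camera with Benjamini-Hochberg adjustment) and 19 with the block, by camera. At the preset correlation the sperm, cuticle collagen, adult-stage collagen, DAF-16 target and neuropeptide lists kept theirs by camera in each of these alternatives. They also kept theirs without each of the 6 libraries and under the length correction, with and without the block. None of them passed camera with an estimated correlation (adjusted p = 0.314 to 0.713). In the DAF-16 target and neuropeptide lists the median of at least 1 diquat library lay above that of control 3. In the sperm, cuticle collagen and adult-stage collagen lists all diquat medians lay below those of the control libraries. Among the 26 named genes and the 46 lists under camera the block changed the calls of hsp-16.2 and of the 5 lists given with a blocked camera call, and no others. Of 26 named genes DESeq2 changed the call of 1 (ssp-11), DESeq2's size factors of 2 (mtl-1 and ssp-34) and the length correction of 5 (mtl-1, cnc-4, col-185, ssp-16 and ssp-34). At 23390547 to 24593469 counts and 3 libraries per group, changes of 1.5-fold were mostly missed without the block in simulated data (27% recovered). With replicate effects added 6% were recovered without the block and 58% with it.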

Other observations

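The tests of a smaller germline, of fewer animals at the last molt and of 1 same-numbered pair, all length corrections, the named-gene rule in the blocked fit and the other genes named for calls in these fits were chosen after the results were seen. The lists not described above did not pass camera without the block or the length correction, with medians from -0.21 (intestine) to 0.09 (F-box genes). Of the genes for energy metabolism, the tricarboxylic acid cycle list had a median log2 fold change of -0.07 over 24 members (camera adjusted p = 0.331; 0.0456 with the block and the length correction, and 0.560 with an estimated correlation too) and glycolysis and gluconeogenesis one of -0.09 over 21 (camera adjusted p = 0.168; blocked adjusted p = 0.0371, and 0.555 with the block and an estimated correlation). Fatty acid synthesis and desaturation had a median of 0.05 over 21 members, negative with upper-quartile scaling (camera adjusted p = 0.122). With the block the desaturase genes fat-5 and fat-6 and the elongase gene elo-5 rose. fat-5 was at 11.7 ± 0.790 and 17.2 ± 2.77 CPM (n = 3; edgeR adjusted p = 0.227; blocked 0.00180). Lipolysis and fatty acid oxidation had a median of 0.04 over 49 members, negative with upper-quartile scaling and with the length correction (camera adjusted p = 0.586), and acs-2 and acdh-9 fell with the block. Intestinal genes had a median of -0.21 over 10 members (camera adjusted p = 0.141), and with the block asp-1, act-5, vha-6 and cpr-1 fell while the peptide transporter gene pept-1 rose.

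Neuronal genes had a median of 0.01 and a mean of 0.02 over 20 members, while camera ranked them lower (adjusted p = 0.842), and the median was -0.05 with upper-quartile scaling and -0.06 with the length correction. Dopaminergic genes had a median of 0.04 over 5 members, negative under the same alternatives (camera adjusted p = 0.686). Pharynx genes had one of -0.16 over 14 (camera adjusted p = 0.107; 0.0472 with the block and the length correction, and 0.584 with an estimated correlation too). Stress signalling regulators had a median of 0.08 over 23 members, -0.02 with the length correction (camera adjusted p = 0.303), and pmk-1, nsy-1, sir-2.1 and daf-18 rose with the block. With the length correction as well nsy-1 and daf-18 lost these calls (edgeR adjusted p = 0.212 and 0.178) and pdk-1, aak-2 and hlh-30 fell (0.0105, 0.00342 and 0.000637). The proteasome list had a median of -0.05 over 33 members and the autophagy list 0.05 over 26, negative with upper-quartile scaling (camera adjusted p = 0.303 and 0.625), and with the block epg-2 rose and sqst-1 fell. Apoptosis genes had a median of 0.04 over 14 members, negative with upper-quartile scaling and the length correction (camera adjusted p = 0.686), and ced-12 rose with the block. The hypoxia list had a median of -0.02 and a mean of 0.01 over 12 members (camera adjusted p = 0.822). Nuclear hormone receptors had a median of 0.07 over 171, with nhr-260 and nhr-31 higher and nhr-88 lower in the block, F-box genes 0.09 over 138, with fbxa-215 higher in the block, and chemoreceptors -0.06 over 24 (camera adjusted p = 0.0839, 0.126 and 0.331). Histone genes had a median of -0.02 over 36 members, which was 0.14 with the length correction (camera adjusted p = 0.615 and 0.0174; 0.818 with the length correction and an estimated correlation).

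The first pattern is the fall of sperm and collagen genes. Trends with transcript length do not account for its size. The sperm and cuticle collagen medians were -1.22 and -0.44 before and -1.04 and -0.40 after the length correction. Falls went from 24 to 16 sperm genes and from 39 to 34 collagens, and the sperm list lost its fry call (adjusted p = 0.0729). The median of the called genes was -1.36 before and -1.28 after the correction (95% bootstrap interval -1.34 to -1.19). That change had to be small, since these genes were chosen for their fall and the shortest length decile had a median of -0.12. A changed split of reads between msp copies does not account for the fall of msp genes. The log2 ratio of their summed CPM was -1.51 to -1.09 in the same-numbered libraries. For a smaller germline, the oocyte and germline medians were -0.001 and 0.10 (-0.06 and 0.03 after the length correction), against -1.22 for sperm genes. The lower of their bootstrap bounds was -0.031, but it resamples genes and holds no spread between libraries. The lowest library median of either list was -0.22 (oocyte genes, diquat 3), against -0.11 in control 3. A germline loss as large as the fall of sperm genes is argued against, and a small one cannot be excluded. Fewer animals near the last larval molt or at the close of sperm production among the diquat worms may underlie the first pattern. This stays open. The molting list had a median of -0.0888 (interval -0.15 to -0.01), which decides nothing. Its called members went both ways in the blocked fit and only down with the length correction as well. The stage of the worms is not given in the sources used here. An effect of diquat on these genes at equal stage is equally open and was not tested.

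The second pattern is the set of 598 genes that rose with the block and not in the edgeR test without it. Of these, spp-17 also rose with the length correction alone. Transcript length could account for part of it: with the block and the length correction 451 genes rose, 333 of them among the 598, while 265 of the 598 and all 16 enriched terms among the rises were lost. For some genes the adjusted p-values also differed widely between these fits at like fold changes, so length is not their only difference. A source in 1 same-numbered pair cannot be told apart from a shared rise. The blocked fit called 15 genes higher without pair 1, against 329 and 436 without pairs 2 and 3. Genes chosen in the other pairs lay above all tested genes by 0.11 in pair 2 (interval 0.09 to 0.12), 0.23 in pair 1 and 0.15 in pair 3, and the lowest bound missed the limit of 0.1 set for the test. A first form of that test, on the 598 genes themselves, gave medians of 0.28, 0.38 and 0.34 without pairs 1, 2 and 3 against 0.33 with all, and was set aside because those genes had been chosen with all pairs.

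The third pattern is the grouping of the libraries. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split had 121 genes past the threshold against 1199 at most in the others, so 2 of the 10 had as many, and it had 102 against 34 over 2-fold (1 of 10), 19 against 22 lists (3 of 10) and 1 against 29 terms (2 of 10). The split of control 1, control 2 and diquat 2 from the rest gave the 1199, several times the real count, and keeps pairs 2 and 3 whole on opposite sides, which points to a structure of the samples other than the groups. The other splits that part only 1 pair called 0 genes. Among them is that of control 1, control 2 and diquat 1, with pairs 1 and 3 whole on opposite sides. Keeping pairs whole therefore does not by itself account for the 1199. The 4 splits that part all pairs are too few as well: the other 3 gave at most 0 genes, 0 over 2-fold, 15 lists and 0 terms, and with the block 0 genes against 1128 (1 of 4).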
